A study of Papio anubis with 588 samples.

How the data were processed

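RNA was extracted from frozen tissue, and libraries were made and sequenced in a pair of batches, per the labels' protocols. Batch 1 held 16 animals with an unstranded kit and single-end reads of 50 bases, and batch 2 held 83 animals with a stranded kit and paired-end reads of 50 bases. All libraries of an animal shared their extraction, library and sequencing batches, per the labels' protocols. The submitters' processing notes name FastQC, STAR 2.7.7a and featureCounts. Their settings, the genome build, the annotation and whether counting used strand are not given in the sources used here, so genes that overlap on opposite strands and near-identical copies (serum amyloid, globin, IFIT, myosin and troponin genes) are uncertain.

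The authors deposited whole-number counts per gene with no normalization, as a table of 588 libraries and a table of the 570 libraries that passed their quality control, whose criteria are not given in the sources used here. The values shared by both tables were identical. Each table has 34178 genes, of which 33824 (99%) match a symbol of the RefSeq annotation of assembly Panubis1.0, used here for names only, and 17049 carry provisional LOC names. Each column was matched to its animal, tissue and time by its name. The labels do not say which animals form each batch. The first axis of the animals' mean expression over both diets (26.4% of the variance) separated 16 animals from 83, with a gap of 32.9 between the groups and 5.0 for the next largest, and these were taken as batches 1 and 2.

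Tests used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 for checks and figures. For each tissue, libraries of animals with both times were scaled by TMM, genes were filtered by filterByExpr with the diet as group (minimum count 10), and the diet was tested by edgeR's quasi-likelihood test with 1 common dispersion and the animal as a block, adjusted by Benjamini-Hochberg at 0.05. Standard errors were taken from the fold change and the F statistic. The difference of the diet effect between tissues was tested by limma with a trend on the difference of within-animal changes of log2 CPM (prior count 2). Gene lists were tested by camera with a preset correlation of 0.01 on within-animal changes, for lists with at least 4 tested genes, adjusted within a tissue, and again with an estimated correlation. The fry test of limma, planned beside camera, asks whether a list's genes changed, without comparing them with other genes. It was adjusted within a tissue as well. The 40 lists held 635 entries, 565 of them with a gene in the tables. A list score is the mean log2 CPM of its genes tested in that tissue. In liver 18 of 35 lists passed camera, and 6 with an estimated correlation. In muscle the counts were 7 of 35 and 0, with 2 at an unadjusted p under 0.05 by camera with an estimated correlation, and in adipose tissue 9 of 37 and 0, with 4.

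The groups, the tests, the gene lists, the rule for named genes and the alternatives to try were fixed before the data were examined. The rule took, per tissue, the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with a symbol, a mean of at least 5 CPM and a change in that direction in at least 70% of animals. It added 28 anchor genes whatever their result, of which 23, 18 and 22 were tested in liver, muscle and adipose tissue, and up to 4 members of each list that passed camera. For each difference between tissues it took the 5 largest. This gave 99, 59 and 68 genes, some of which are not reported here. Members of lists named because they moved against the list (FN1, MYH2, ECI1, APOE, APOC1, ACP5, FABP5 and, in liver, IL1RN) and genes named for the change in all tissues were chosen after their values were seen.

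Libraries of an animal come from the same animal by the labels, which sets the pairing. As a check, deviations from the group means of an animal's libraries at the 2 times correlated at a median of 0.617 in liver, 0.592 in muscle and 0.568 in adipose tissue, against 0.0165, 0.0373 and 0.0295 for different animals of a batch. The correlation was over 0.1 in 84 of 84, 93 of 95 and 93 of 95 animals, and the best match of an animal's 0-year library among all 2-year libraries was its own in 76 of 84, 66 of 95 and 57 of 95 animals, so this check does not identify each animal. Libraries of 0 of 99 animals disagreed on Y-linked expression, and 0 pairs of libraries were identical.

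The edgeR test was tested on simulated data, 1500 genes drawn from the real means and library sizes with 200 changed. For the diet effect in liver it recovered 74% of genes changed by 0.2 on the log2 scale and 97% of those changed by 0.5, with 4.47% false calls. For muscle these shares were 63%, 99% and 6.9%, and for adipose tissue 68%, 97% and 3.51%.

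The alternatives so fixed were RLE size factors, limma-voom, no filter on low counts (genes with at least 1 count, limma-voom), a stricter filter of mean CPM 1, no animal block, DESeq2 with no block, all libraries that passed quality control with no block, all libraries before quality control and each batch alone (both limma-voom), a prior count of 0.5, an estimated correlation for lists, and a minimum log2 change of 0.5. Alternatives chosen after seeing the data left out animals in doubt (markers of another tissue above 0.1% of counts and 10 times the tissue's median, or own libraries correlating at 0.1 or less, which gave 5, 5 and 10 animals in liver, muscle and adipose tissue), used limma on within-animal changes, and added score changes of other cell types as covariates. Permutation tests of correlations and of list differences were two-sided with 100000 resamples.

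The spread between animals at 0 and 2 years was compared by the correlation of the sum and the difference of an animal's batch-adjusted log2 CPM, for genes with a mean of at least 5 CPM. It was computed in 2 versions in each of 3 tissues. The version on ranks was chosen before any value was seen, because the version on the values themselves is sensitive to single outlying libraries. Its prediction was a plain comparison of the numbers of genes with a wider and with a narrower spread in liver. That rule was changed after the result was seen, to ask also for a binomial test, and was then restored, and the binomial p is given beside the counts.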

Results

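Gene expression was measured by RNA sequencing in biopsies of liver, muscle and adipose tissue from 99 captive olive baboons (Papio anubis), an Old World monkey used as a model of human lipid metabolism. Each animal was sampled on a diet low in cholesterol and fat (LCLF) at 0 years and again after 2 years on a diet high in both (HCHF). The authors' quality control kept 570 of the 588 libraries. These were 95 LCLF and 87 HCHF libraries of liver, 96 and 98 of muscle, and 99 and 95 of adipose tissue. The total count per library, in M (mega-counts), ranged from 6.51 to 38.46 M with a median of 19.5 M, and the group medians lay between 18.21 and 20.82 M. The 93 libraries of the first library batch were shallower, with a median of 10.95 M, than the 477 of the second, with a median of 20.1 M. The diet was tested within animals sampled at both times, 84 for liver, 95 for muscle and 95 for adipose tissue. Animals without the change of diet were not analysed here, so a difference between HCHF and LCLF libraries also holds 2 years of age and calendar time.

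The first comparison asked which liver transcripts differed after the HCHF diet. Macrophage genes were higher and genes of cholesterol synthesis were lower. With an estimated correlation the call of the first of these lists held and that of the second did not. The fry test, which makes no comparison with other genes, gave them adjusted p = 2.39e-22 and 6.12e-16. CHIT1, a chitinase secreted by activated macrophages, rose 12.5-fold (log2 fold change 3.64 ± 0.21, SE, n = 84 animals, as for all liver values) and was higher in 82 of the 84 animals. Its mean level was 0.87 CPM in LCLF and 10.71 CPM in HCHF libraries. GPNMB, a glycoprotein of lipid-laden macrophages, rose by 2.07 ± 0.12 on the log2 scale. SQLE, the squalene epoxidase of the cholesterol pathway, fell by 1.29 ± 0.14 and was lower in 71 animals. Of 14919 genes tested, 3360 were higher and 4117 lower after the HCHF diet, 1284 and 126 of them by at least 0.5 on the log2 scale, and with the libraries left out by the authors 603 were lower by at least 0.5. In the left-out liver libraries hepatocyte markers took at most 0.813% of counts.

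Of 19 cholesterol synthesis genes, 18 fell and 0 rose, both over all genes tested and adjusted over the list alone (camera adjusted p = 5.33e-13; adjusted p = 0.0558 with an estimated correlation). Besides SQLE, these included FDPS, which makes farnesyl diphosphate (-0.78 ± 0.08), and DHCR7, a late reductase of the pathway (-0.80 ± 0.10). Of 12 genes of LDL uptake and its control by SREBP, 8 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 0.188 with an estimated correlation). NPC1L1, a sterol transporter, fell by 0.54 ± 0.07. The member that rose was MYLIP, a ubiquitin ligase (0.67 ± 0.06). MYLIP is also in the list of sterol efflux and LXR target genes, of which 7 rose and 2 fell of 13, again with the same counts adjusted over the list alone (adjusted p = 0.174 with an estimated correlation). The members that fell were the apolipoprotein genes APOE (-0.12 ± 0.04) and APOC1 (-0.17 ± 0.04). ABCG1, a sterol exporter, rose by 1.13 ± 0.09 and PLTP, the phospholipid transfer protein, by 0.89 ± 0.07. The sterol transporters of bile ABCG5 (0.06 ± 0.07) and ABCG8 (-0.03 ± 0.07) did not pass the test, and neither did the lipogenic genes FASN (-0.12 ± 0.21) and SCD (-0.30 ± 0.30). With no animal block FASN in liver was -0.85 and SCD in liver -0.84, and both passed. SREBF1, a transcription factor of lipogenesis, rose by 0.62 ± 0.13, and its value of 0.37 with no block did not pass. Of 15 genes of bile acid synthesis and transport, 8 fell and 0 rose, also adjusted over the list alone, among them HSD3B7 (-0.25 ± 0.04; adjusted p for the list = 0.211 with an estimated correlation).

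Genes of mitochondrial metabolism were lower in liver by small amounts. Of 34 oxidative phosphorylation genes, 30 fell and 0 rose, also adjusted over the list alone, with SDHB of complex II at -0.23 ± 0.03 (adjusted p for the list = 0.211 with an estimated correlation). Of 26 fatty acid oxidation genes, 20 fell and 0 rose, or 21 and 0 adjusted over the list alone (adjusted p = 0.291 with an estimated correlation), with EHHADH at -0.25 ± 0.05. PPARGC1A, a coactivator of mitochondrial genes, fell by 0.53 ± 0.07. SDS, a serine dehydratase, had the largest change among the named genes that fell in liver (-1.62 ± 0.23, and -0.76 with no animal block). ARG2, a mitochondrial arginase, fell by 1.33 ± 0.25, but its value was 0.11 with no animal block and did not pass. Of 12 hepatocyte markers, 7 fell and 0 rose, also adjusted over the list alone, with CPS1 of the urea cycle at -0.51 ± 0.06 (adjusted p for the list = 0.4 with an estimated correlation).

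Markers of immune cells rose in liver. Of 13 macrophage markers, 12 rose and 0 fell (camera adjusted p = 7.85e-17), among them CD68 (1.48 ± 0.11) and the complement gene C1QC (1.42 ± 0.10). The mean change of the macrophage score, the mean log2 CPM of the list, was 0.853 ± 0.129 in batch 1 (n = 13) and 1.24 ± 0.0951 in batch 2 (n = 71). Of 13 markers of lipid-associated macrophages, 10 rose and 2 fell, with TREM2, a lipid receptor, at 1.31 ± 0.16 and MMP9, a matrix protease, at 1.71 ± 0.14, while SPP1 (0.05 ± 0.14) did not pass. The members that fell were APOC1 and ACP5, an acid phosphatase (-0.10 ± 0.04). Levels were low, with mean CPM of 0.33 (LCLF) and 0.84 (HCHF) for TREM2, 0.44 and 1.38 for MMP9, and 0.94 and 1.04 for SPP1. All 12 markers of T and NK cells rose, with CD4 at 1.29 ± 0.10, CD8A at 0.85 ± 0.08 and CD3E at 0.80 ± 0.08. All 5 markers of neutrophils rose too, with CSF3R at 1.46 ± 0.13. Of 12 inflammatory genes, 8 rose and 1 fell, with the adhesion molecule ICAM1 at 0.74 ± 0.06 and IL1RN, the IL-1 receptor antagonist, the member that fell (-0.35 ± 0.14, and -0.292, which did not pass, without the animals in doubt). These counts were the same adjusted over the list alone, and the calls of all 5 lists held with an estimated correlation. Of 19 interferon-stimulated genes, 11 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.394 with an estimated correlation), with MX2 at 0.69 ± 0.06. FABP4, a fatty acid carrier of adipocytes and macrophages, rose by 2.26 ± 0.19, with a value of 0.56 in batch 1 alone that did not pass the test and 3.27 in batch 2 alone. Without the 5 animals whose liver libraries were in doubt, 1 of which held 0.229% of counts on adipocyte markers, the value of FABP4 in liver was 2.02. Of 5 adipocyte markers in liver, 1 rose and 2 fell, also adjusted over the list alone, with a median of -0.11 and no call. Their mean score change was 0.407, with -0.132 in batch 1 and 0.505 in batch 2.

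Endothelial and stromal genes rose in liver as well. All 11 endothelial markers rose, with PECAM1 at 0.85 ± 0.06, and the call held with an estimated correlation. All 11 markers of fibroblasts and stellate cells rose, with RELN, a stellate cell gene, at 0.60 ± 0.07 (adjusted p = 0.069 with an estimated correlation). Of 22 extracellular matrix genes, 21 rose and 1 fell, with TGFB1 at 0.92 ± 0.07, COL1A1 at 0.66 ± 0.14 and FN1, fibronectin, the member that fell (-0.16 ± 0.06; adjusted p = 0.151 with an estimated correlation). Of 7 smooth muscle markers, 6 rose and 0 fell, with ACTA2 at 0.93 ± 0.19 (adjusted p = 0.273 with an estimated correlation), and of 5 Schwann cell and nerve markers, 4 rose and 0 fell, with PRX at 0.60 ± 0.09 (adjusted p = 0.14 with an estimated correlation). The counts of these 5 lists were the same adjusted over the list alone. Of 8 bile duct markers, 1 rose and 0 fell, and that list did not pass. The erythroid genes HBB and ALAS2, which mark blood in a biopsy, had a mean score change of 1.09 ± 0.149.

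The liver values came from edgeR's quasi-likelihood test with the animal as a block and Benjamini-Hochberg adjustment at 0.05. With no animal block 2325 genes were lower, and in batch 1 alone (13 animals, limma-voom) 640 were higher and 294 lower. With the score changes of other cell types as covariates in limma, chosen after seeing the data, 25 genes were higher and 19 lower.

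**Figure D1:**
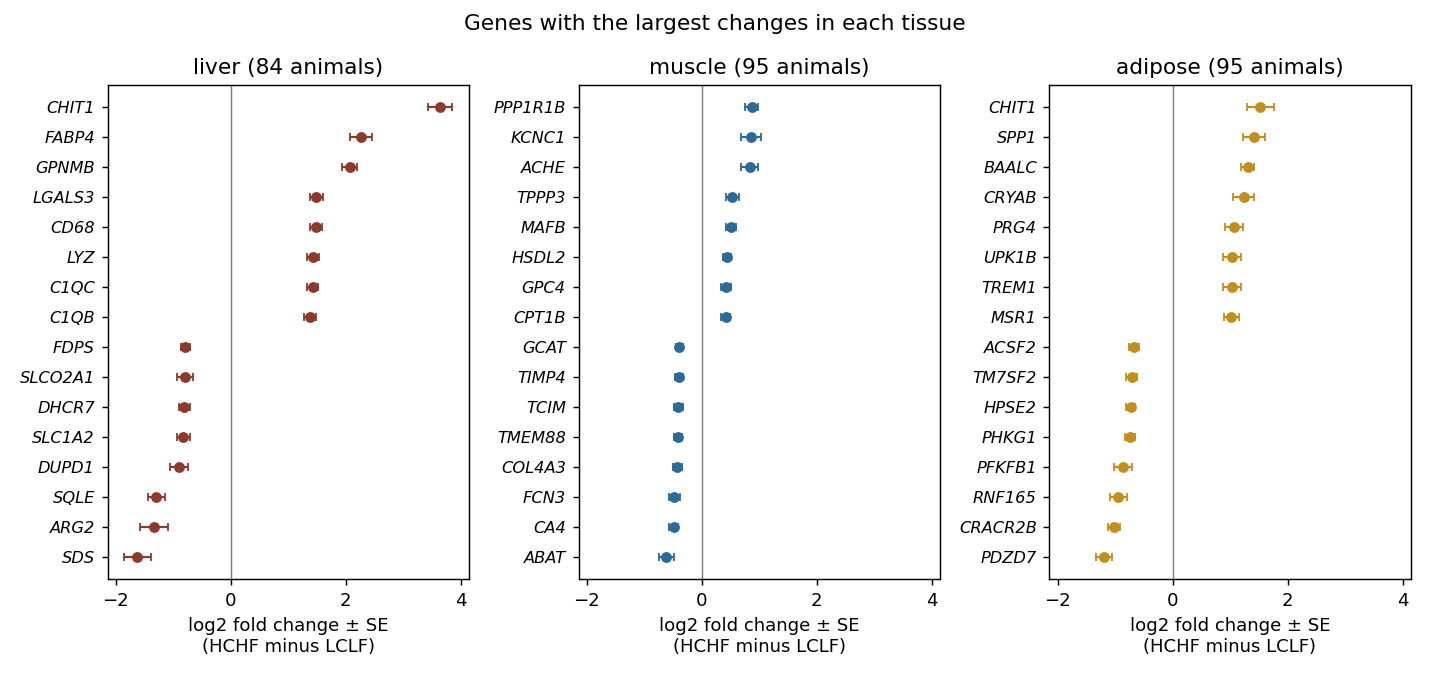
Log2 fold changes (HCHF minus LCLF) with standard errors for the named genes with the largest rises and falls in liver (84 animals), muscle (95) and adipose tissue (95). CHIT1 had the largest rise among the genes drawn for liver (3.64) and for adipose tissue (1.52), and every gene drawn for muscle lies within 0.87 of 0.

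The second comparison asked the same of muscle. CPT1B, which carries fatty acids into muscle mitochondria, rose by 0.42 ± 0.08 (SE, n = 95 animals, as for all muscle values) and was higher in 71 animals. Genes of fast fibres fell, with MYLPF, the fast light chain of myosin, at -0.33 ± 0.07. Endothelial genes fell, with ESAM, an adhesion molecule of vessels, at -0.29 ± 0.06. Collagen and macrophage genes rose, with COL1A1 at 0.53 ± 0.15 and CSF1R, a macrophage receptor, at 0.45 ± 0.12. The fast fibre, endothelial, matrix and macrophage lists passed camera, but none of these 4 calls held with an estimated correlation (adjusted p = 0.589 for each). The fry test, which makes no comparison with other genes, gave them adjusted p = 0.00137, 0.00359, 0.0371 and 0.0192. It also passed lists that did not pass camera, among them the inflammatory list (fry adjusted p = 0.0234). Of 13621 genes tested, 1006 were higher and 1122 lower, 83 and 16 of them by at least 0.5, where no animal block gave 245 and 10 and DESeq2 with no block 159 and 8.

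Of 14 fast fibre genes, 9 fell and 1 rose, also adjusted over the list alone, and the member that rose was MYH2, a myosin of fast oxidative fibres (0.19 ± 0.07), which did not pass without the animals in doubt (adjusted p = 0.0515). Of 9 slow fibre genes, 0 rose and 0 fell in edgeR, also adjusted over the list alone, with 0 at an unadjusted p under 0.05, and the mean change of the list's score was 0.00406 ± 0.0923. Of 26 fatty acid oxidation genes, 8 rose and 1 fell, or 11 and 2 adjusted over the list alone, with HADHA, the trifunctional protein, at 0.25 ± 0.04. Of 34 oxidative phosphorylation genes, 10 fell and 0 rose, or 12 and 0 adjusted over the list alone, with NDUFA6 at -0.15 ± 0.04. Of 11 endothelial markers, 8 fell and 0 rose, or 11 and 0 adjusted over the list alone, with EMCN at -0.26 ± 0.06. Of 21 extracellular matrix genes, 5 rose and 0 fell, or 7 and 0 adjusted over the list alone, with COL3A1 at 0.41 ± 0.11. Of 11 macrophage markers, 7 rose and 0 fell, or 8 and 0 adjusted over the list alone, with CD68 at 0.44 ± 0.11. Of 7 markers of T and NK cells, 4 rose and 0 fell, also adjusted over the list alone, with PRF1, perforin, at 0.54 ± 0.11. PRF1 had a low mean level in muscle, 0.57 CPM (LCLF) and 0.88 CPM (HCHF). The slow fibre list did not pass camera. The other lists of muscle given here passed, each with an adjusted p = 0.589 with an estimated correlation. The member of the fatty acid oxidation list that fell was ECI1, an isomerase of unsaturated fatty acids (-0.14 ± 0.05), which did not pass without the animals in doubt (adjusted p = 0.0533).

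Single genes with the largest changes in muscle included PPP1R1B, a phosphatase inhibitor (0.87 ± 0.12), ACHE, the acetylcholinesterase (0.83 ± 0.15), and KCNC1, a potassium channel (0.86 ± 0.17). ABAT, a GABA transaminase, fell by 0.61 ± 0.13, but did not pass with no animal block (-0.08). CA4, a carbonic anhydrase of capillaries, fell by 0.49 ± 0.08. SREBF2, a transcription factor of sterol genes (0.01 ± 0.05), did not pass. The muscle test was the same as in liver. With no animal block 504 genes were higher and 164 lower, and ESAM, EMCN and NDUFA6 did not pass, while with the libraries left out by the authors MYLPF was 0.41 and did not pass. Of these left-out libraries, the LCLF muscle library of animal 15545 held 0.0435% of counts on myocyte markers and that of 12218 held 20.1%. In batch 1 alone (16 animals, limma-voom) 13 genes were higher and 3 lower, and in batch 2 alone (79 animals) 761 and 672. With the score covariates these counts were 275 and 308.

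The third comparison was that of adipose tissue, where macrophage and matrix genes rose and several lipogenic genes fell, though the fatty acid synthesis list did not pass. The macrophage and matrix lists passed camera, but not with an estimated correlation. The fry test, which makes no comparison with other genes, gave them adjusted p = 2.99e-05 and 5.74e-09. CHIT1 rose by 1.52 ± 0.24 (SE, n = 95 animals, as for all adipose values), and SPP1, osteopontin, a cytokine of lipid-associated macrophages, by 1.42 ± 0.20. LEP, the adipocyte hormone leptin, rose by 0.99 ± 0.22 and was higher in 70 animals. FASN, the fatty acid synthase, fell by 0.71 ± 0.20 and was lower in 64 animals. Of 16827 genes tested, 3190 were higher and 3404 lower, 296 and 117 of them by at least 0.5.

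Of 13 macrophage markers, 12 rose and 0 fell, also adjusted over the list alone, with MSR1, a scavenger receptor, at 1.02 ± 0.13 and CD163 at 0.59 ± 0.10 (adjusted p for the list = 0.443 with an estimated correlation). Of 13 markers of lipid-associated macrophages, 10 rose and 2 fell, or 11 and 2 adjusted over the list alone, with TREM2 at 0.62 ± 0.12 and the apolipoprotein gene APOC1 (-0.63 ± 0.16) and the fatty acid carrier FABP5 (-0.23 ± 0.09) the members that fell (adjusted p for the list = 0.166 with an estimated correlation). FABP5 in adipose tissue did not pass without the animals in doubt (adjusted p = 0.0515). Of 5 neutrophil markers, 4 rose and 0 fell, with CSF3R at 0.83 ± 0.15 (adjusted p = 0.443 with an estimated correlation), and of 13 inflammatory genes, 6 rose and 0 fell, with IL1RN, the IL-1 receptor antagonist, at 0.65 ± 0.15 (adjusted p = 0.869 with an estimated correlation). Of 22 extracellular matrix genes, 17 rose and 0 fell, with COL1A2 at 0.45 ± 0.08 (adjusted p = 0.166 with an estimated correlation). Of 11 fibroblast markers, 9 rose and 0 fell, or 9 and 1 adjusted over the list alone, with PI16 at 0.74 ± 0.14 (adjusted p = 0.166 with an estimated correlation). Of 11 endothelial markers, 7 fell and 0 rose, with CLDN5 at -0.23 ± 0.06 (adjusted p = 0.869 with an estimated correlation). The counts for neutrophil, inflammatory, matrix and endothelial genes were the same adjusted over the list alone. Of 12 T and NK cell markers in adipose tissue, 2 rose and 0 fell, also adjusted over the list alone. That list did not pass (camera adjusted p = 0.289).

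Markers of tissues beside the fat also rose. All 5 erythroid markers rose, with HBB, beta globin, at 0.89 ± 0.18 (adjusted p for the list = 0.399 with an estimated correlation), and of 8 markers of the mesothelium, the lining of the abdominal cavity, 6 rose and 0 fell, with BNC1 at 0.72 ± 0.13 (adjusted p = 0.53 with an estimated correlation). Both counts were the same adjusted over the list alone. Of 9 adipocyte markers, 1 rose and 2 fell, also adjusted over the list alone, and the list did not pass. ADIPOQ, adiponectin, fell by 0.25 ± 0.09 with the animal block and did not pass with no block. Of 20 fatty acid synthesis genes, 6 fell and 1 rose, also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.121). The member that rose was SREBF1 (0.36 ± 0.12), which did not pass with no block (0.10). SCD had a value of -0.65 ± 0.36 that did not pass, and -0.99 with no block, which did. SAA1, a serum amyloid with near-identical copies whose reads could be shared, fell by 1.23 ± 0.17. Of 19 cholesterol synthesis genes, 7 fell and 0 rose, also adjusted over the list alone, and the list did not pass. TM7SF2 of this list fell by 0.71 ± 0.09 in adipose tissue and was lower in 77 animals, while SQLE (0.01 ± 0.08) did not pass.

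Other large changes in adipose tissue included BAALC (1.31 ± 0.12), CRYAB, a small heat shock protein (1.23 ± 0.19), and PDZD7, a scaffold protein (-1.19 ± 0.14). CRACR2B, a calcium channel regulator, fell by 1.02 ± 0.10 and was lower in 86 animals. The test was the same as in liver. With no animal block, 1960 genes were higher and 1918 lower. In batch 1 alone (16 animals, limma-voom) 0 were higher and 1 lower, with 1541 of 15601 genes at an unadjusted p under 0.05, and in batch 2 alone (79 animals) 2907 and 3245. With the score covariates 415 were higher and 396 lower, and FASN in adipose tissue was 0.10 and did not pass.

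**Figure D2:**
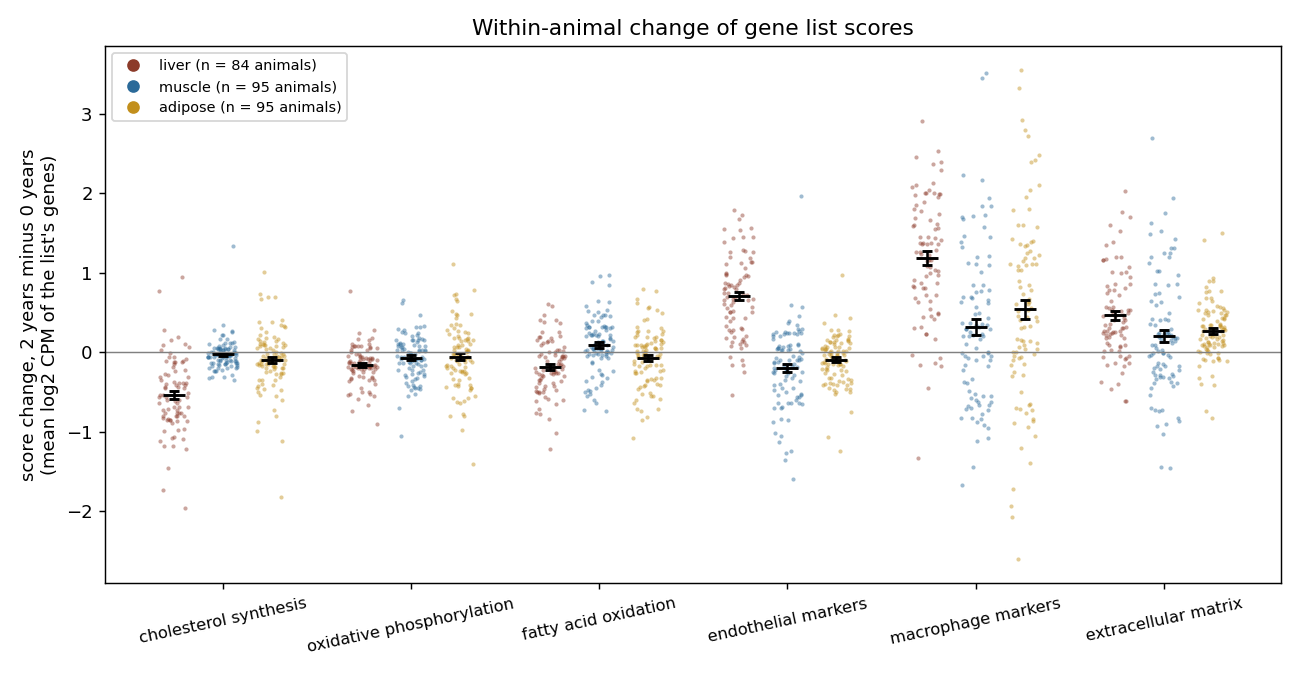
Change of the mean log2 CPM of 6 gene lists (2 years minus 0 years), each point an animal in liver (84), muscle (95) or adipose tissue (95), with the mean and its standard error in black. The cholesterol synthesis score had its lowest mean in liver (-0.533), and the mean endothelial score change was 0.705 in liver, -0.197 in muscle and -0.0955 in adipose tissue.

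The next comparisons asked whether the change differed between tissues of the same animals, with limma on the difference of within-animal changes. Liver and muscle differed most in FABP4, whose change was 2.55 ± 0.21 larger in liver (80 animals), and in GPNMB (1.72 ± 0.19). The change of LGALS3, galectin-3, was 1.33 ± 0.13 larger in liver, and that of CD300LG, a receptor of endothelial cells, 1.29 ± 0.13. Against adipose tissue (82 animals), the change in liver was larger for CHIT1 by 1.97 ± 0.32 and lower for SQLE (-1.30 ± 0.17) and for PRG4, a lubricating glycoprotein (-1.32 ± 0.17). Between adipose tissue and muscle (91 animals), the largest differences were in CRYAB (1.36 ± 0.17) and UCHL1, a ubiquitin hydrolase (1.19 ± 0.18). A larger or less negative change in liver than in muscle was called for 2101 of 12553 genes and the opposite for 2057. For liver and adipose tissue these counts were 2897 and 2431 of 14102, and for adipose tissue and muscle 767 and 942 of 13190.

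Gene lists also differed between tissues, in sign-flip permutation tests over 101 differences chosen after their values were seen, where 1e-05 is the smallest p possible and 6.7e-05 its adjusted value. The endothelial score change was 0.88 ± 0.08 higher in liver than in muscle and 0.79 ± 0.07 higher than in adipose tissue, with adjusted p = 6.7e-05 for each. It was 0.685 and 0.922 in batches 1 and 2 against muscle, and 0.59 and 0.831 against adipose tissue. The cholesterol synthesis score change was lower in liver than in muscle (-0.51 ± 0.06) and adipose tissue (-0.42 ± 0.06), with adjusted p = 6.7e-05 for each, and -0.635 and -0.482 within the batches against muscle and -0.606 and -0.382 against adipose tissue. The fatty acid oxidation score change was lower in liver than in muscle (-0.26 ± 0.05, adjusted p = 6.7e-05, and -0.342 and -0.239 within the batches) and in adipose tissue than in muscle (-0.15 ± 0.05, adjusted p = 0.016), and did not differ detectably between liver and adipose tissue (-0.09 ± 0.06, adjusted p = 0.18). The macrophage score change was 0.82 ± 0.13 higher in liver than in muscle (adjusted p = 6.7e-05), but 0.32 in batch 1 and 0.921 in batch 2, and 0.675 ± 0.14 higher than in adipose tissue (adjusted p = 0.00013, and 0.721 and 0.666 within the batches). Between adipose tissue and muscle the score changes of macrophage (0.14 ± 0.16, adjusted p = 0.5), endothelial (0.12 ± 0.06, adjusted p = 0.099) and cholesterol synthesis genes (-0.05 ± 0.04, adjusted p = 0.37) did not differ detectably. Those of lipid-associated macrophage markers (0.21 ± 0.07, adjusted p = 0.0084, and 0.0948 and 0.235 within the batches) and of neutrophil markers (0.561 ± 0.152, adjusted p = 0.0018, and -0.0145 and 0.683 within the batches) were higher in adipose tissue. Each score averaged the list members tested in its tissue. Macrophage markers tested were 13 in liver, 11 in muscle and 13 in adipose tissue. In the same order, lipid-associated macrophage markers were 13, 9 and 13, and neutrophil markers 5, 4 and 5. Which genes were averaged may therefore add to the differences of these lists from muscle, and this was not tested. The endothelial (11) and cholesterol synthesis (19) lists had as many tested members in each tissue.

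With no animal block, an interaction of tissue and diet gave 763 genes in place of the 2057 for liver and muscle, 1356 in place of the 2431 for liver and adipose tissue, and 113 and 159 for adipose tissue and muscle. HBB, whose change was 1.12 ± 0.27 larger in adipose tissue than in muscle, and CHI3L1, a chitinase-like protein (-1.08 ± 0.24), did not pass without the block.

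**Figure D3:**
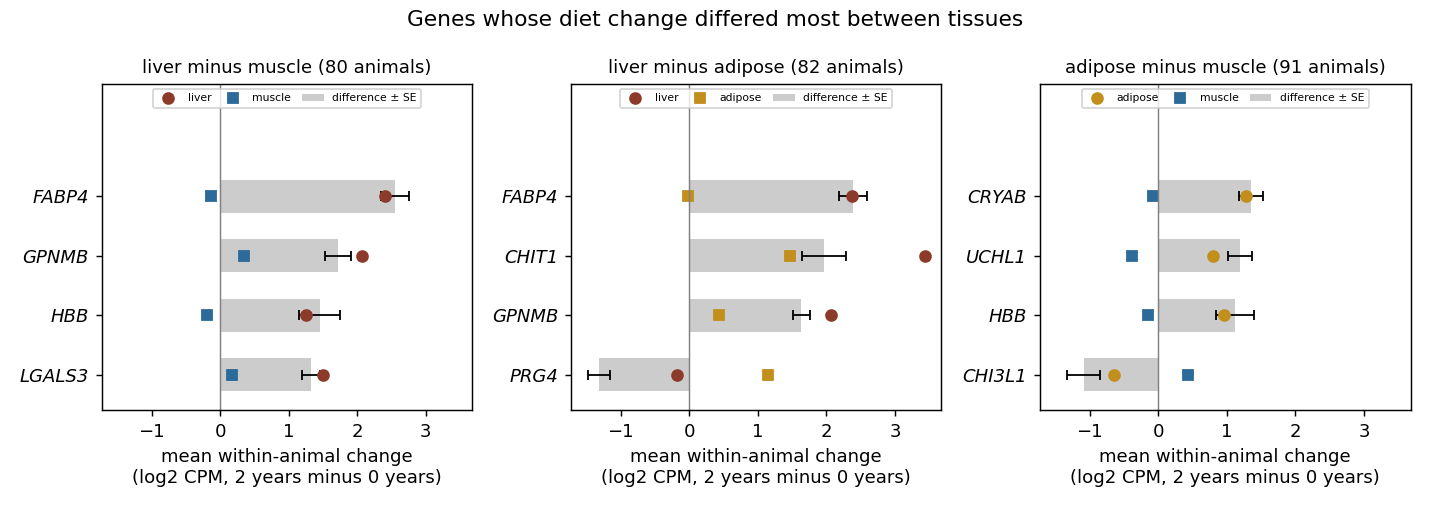
The 4 genes whose change differed most between each pair of tissues of the same animals, with the mean log2 CPM change (2 years minus 0 years) in each tissue as points and the difference with its standard error as grey bars. FABP4 differed most for liver against muscle (2.55) and against adipose tissue (2.39), and CRYAB for adipose tissue against muscle (1.36).

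The last comparison asked which genes changed alike in all 3 tissues. Of 12494 genes tested in each, 168 were higher in all 3 where independent lists would share 37.51, and 159 were lower in all 3 where 64.61 were expected. By the smallest of the 3 changes, a ranking chosen after the values were seen, the integrin gene of myeloid cells ITGAX led the genes higher in all 3, with 0.94 in liver, 0.66 in muscle and 0.66 in adipose tissue. COL1A1 changed by 0.66, 0.53 and 0.51, and VSIG4, a complement receptor of macrophages, by 1.35, 0.56 and 0.61. The mean level of VSIG4 in muscle was low, 0.60 CPM (LCLF) and 0.99 CPM (HCHF). With no animal block the counts were 71, where 9.087 were expected, and 5, where 2.825 were expected, so the lower genes lay close to their expected count. With the block, and at a log2 change of at least 0.5 in each tissue, they were 6, where 0.01779 were expected, and 0, where 9.686e-05 were expected. Across genes, which are not independent replicates, the fold changes had a Pearson r of 0.16 for liver and muscle, 0.30 for liver and adipose tissue, and 0.38 for adipose tissue and muscle.

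**Figure D4:**
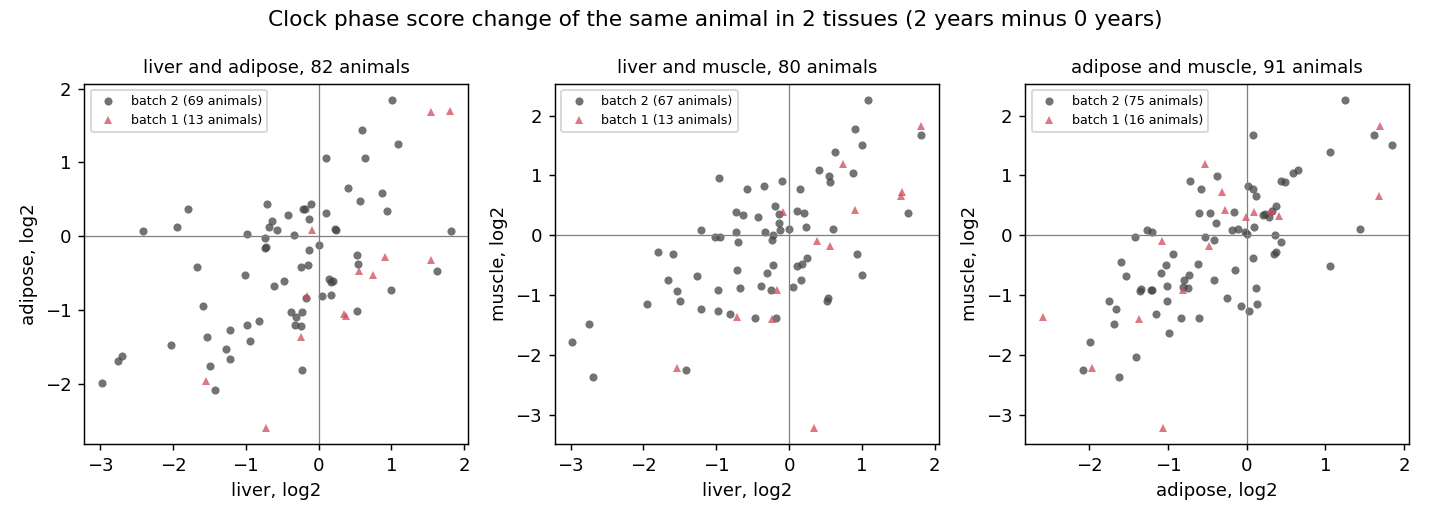
Change of the clock phase score (mean log2 CPM of the PER, NR1D, DBP, TEF and CIART genes minus that of ARNTL, NPAS2 and CLOCK, 2 years minus 0 years) of the same animals in each pair of tissues, with batch 1 animals as triangles and batch 2 animals as circles. The changes correlated between liver and adipose tissue (Pearson r 0.536, 82 animals), liver and muscle (0.599, 80) and adipose tissue and muscle (0.708, 91).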

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

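The tests of a lower share of hepatocyte, adipocyte or muscle fibre RNA and of the library batch were chosen only after the results were seen.

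The diet effect differed between tissues, in tests of the difference itself, for 4158 genes in liver against muscle, 5328 in liver against adipose tissue and 1709 in adipose tissue against muscle. Chance can be excluded for these counts: of 100 exchanges of the 0-year and 2-year labels within animals, only the real one (1 of 100 for each) gave as many, and the highest other counts were 18, 3 and 197. The same holds for the diet effect within a tissue by limma on within-animal changes, with 7385 genes in liver, 2051 in muscle and 6578 in adipose tissue against highest other counts of 3, 4 and 61. Single genes with the largest differences were FABP4 (2.55), GPNMB (1.72), HBB (1.45), LGALS3 (1.33) and CD300LG (1.29) for liver minus muscle. For liver minus adipose tissue they were FABP4 (2.39), CHIT1 (1.97), GPNMB (1.63), PRG4 (-1.32) and SQLE (-1.30), and for adipose tissue minus muscle CRYAB (1.36), UCHL1 (1.19), HBB (1.12) and CHI3L1 (-1.08).

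In liver, markers of macrophages, endothelium, T cells and fibroblasts rose together. A lower share of hepatocyte RNA would raise the markers of every other cell type alike, but the macrophage score rose by 1.1 ± 0.117 more than that of bile duct cells (n = 84). The bile duct list had been seen not to rise before this comparison was chosen. The macrophage score rose by 0.478 ± 0.0554 more than the endothelial, 0.381 ± 0.0652 more than the T and NK cell and 0.621 ± 0.0802 more than the fibroblast score. If markers of other cell types do rise alike, a lower share alone therefore does not give the whole macrophage rise. Whether they would rise alike was not tested. A lower share may account for the part of the rise that these lists have in common, and how much stays open. The score of the erythroid genes HBB and ALAS2 rose by 1.09 ± 0.149, so more blood in the later biopsies stays open. At no change of that score the macrophage score changed by 1.1 ± 0.107, against 1.18 ± 0.084 before. A score of so few genes is noisy, and noise in it would leave this value near the unadjusted one. How much of the macrophage rise blood accounts for is therefore not decided. T and NK cell and neutrophil markers were not tested in this way. The macrophage score change was 0.853 ± 0.129 in the library batch where it was smaller. The libraries of an animal shared a batch, however, so the design fixes this test and it decides nothing. A higher share or activity of macrophages under the diet may remain, as a hypothesis, and so may 2 years of age, which was not tested apart from the diet. The mean change of the cholesterol synthesis score was -0.533 ± 0.0517, and the smaller -0.338 ± 0.0925 at no change of the macrophage, endothelial, T cell and fibroblast scores.

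In adipose tissue, 6 of 20 fatty acid synthesis genes fell and 1 rose, with a mean score change of -0.185 ± 0.119 and a list that did not pass, while macrophage and matrix genes rose. The fatty acid synthesis score changed by -0.176 ± 0.119 relative to the adipocyte markers, whose own score showed no detectable change (-0.00933 ± 0.0998). At this spread a lower share of adipocyte RNA and a fall within adipocytes cannot be told apart for the list as a whole. The lipogenic genes that fell were not tested apart from the list. At no change of the mesothelial and erythroid scores the macrophage score changed by 0.32 ± 0.128, against 0.541 ± 0.12 before, so more mesothelium or blood in the later biopsies may account for part of the rise, and how much stays open.

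In muscle, fast fibre genes fell. The fast minus slow score change was -0.203 ± 0.119, too imprecise to exclude a lower share of muscle fibre RNA. Markers of other cell types moved apart, with a score change of 0.318 ± 0.101 for macrophages and -0.197 ± 0.0511 for endothelium. A lower fibre share alone would raise both, so it does not account for the endothelial fall. Whether it accounts for part of the fast fibre fall stays open. At no change of the slow score the fast score changed by -0.199 ± 0.0477, but the mean change of the slow score itself was 0.00406 ± 0.0923, so this setting moves nothing and decides nothing. Both scores were related across animals (r = -0.334, n = 95). Fewer fast and more slow fibres in the later biopsies and a fall within fast fibres therefore cannot be told apart.

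Among the 18 libraries left out by the authors, 12 values of another tissue's markers exceeded the highest of any kept library of the labelled tissue. Hepatocyte markers took 19.1% and 18.7% of counts in the HCHF adipose libraries of animals 16017 and 17916, where kept libraries reached 0.269%. Myocyte markers in libraries labelled liver took 18.2% (14642, HCHF), 4.03% (14924, HCHF), 17.1% (14948, LCLF), 3.92% (15163, HCHF), 3.99% (15175, HCHF), 13.4% (15292, LCLF), 16.1% (16400, LCLF) and 4.71% (17141, HCHF), where kept libraries reached 0.461%. Adipocyte markers took 0.794% in the HCHF liver library of 17916 (kept, 0.229%) and 1.12% in the LCLF muscle library of 15545 (kept, 0.191%). Hepatocyte markers took at most 0.813% of counts (15292, LCLF) in the 13 left-out libraries labelled liver. Among these, the HCHF libraries of 14473, 14944, 14948 and 17268 held at most 0.0898% on the markers of any of the 3 tissues. The left-out adipose library of 16017 differed from that animal's kept HCHF liver library by a chi-square per gene of 2.72, against at least 15.9 between an animal's liver libraries at the 2 times.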

How the results depend on the processing

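The alternatives that left out animals in doubt, used limma on within-animal changes, or added marker score covariates were chosen only after the results were seen; the others were planned. Under RLE size factors, with the block kept, all named genes kept their side of the threshold, and those that passed kept their direction. The direction of genes that passed in neither fit was not compared. By the same rule, 1128 of 1279 values of named genes in liver held over all alternatives. These counts were 640 of 754 in muscle, 736 of 882 in adipose tissue and 88 of 90 for named differences. Where a cause is not given below, the cause was not tested.

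Without the animal block (edgeR, then DESeq2, then edgeR with all libraries that passed quality control), liver had 2325, 2281 and 2515 genes lower. Muscle had 504, 411 and 583 higher and 164, 132 and 171 lower, and adipose tissue 1960, 1995 and 1947 higher and 1918, 1857 and 1909 lower. Without the block the tissue differences fell to 763 genes with a lower (more negative) change in liver than in muscle, 1356 with a lower one in liver than in adipose tissue, and 113 and 159 for adipose tissue and muscle, and the genes changed in all 3 tissues to 71 and 5. With the block, 6 and 0 genes changed in all 3 tissues by at least 0.5 in log2, and without the animals in doubt 103 were lower in all 3. ARG2 in liver turned to 0.11 and, with all libraries, 0.0976. Of the named genes reported here, no block ended the calls of SLCO2A1 and SREBF1 in liver, of ABAT, CDH5, COX5A, EMCN, ESAM, NDUFA1, NDUFA6, NDUFB9, NKG7 and VWF in muscle, and of ABCA1, ADIPOQ, CXCL8, KRT19, ROBO4, S100A8, S100A9, SREBF1 and WT1 in adipose tissue, and of HBB and CHI3L1 between adipose tissue and muscle. It made calls of FASN, SAA1 and SCD in liver, APOA1 and INSIG1 in muscle and SCD in adipose tissue, and of the myocyte list in muscle and the cell cycle and bile duct lists in adipose tissue. In edgeR, limma and camera without it, the block changed no other call reported here of a gene chosen by the fixed rule, a named difference or a list. For genes named after their values were seen, calls without the block are not given here.

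With no low-count filter (limma-voom), 9735 genes were lower in liver and 7616 in adipose tissue, with more genes tested. Batch 1 alone, with fewer animals, gave 640 higher and 294 lower in liver, 13 and 3 in muscle, and 0 (1541 at an unadjusted p under 0.05) and 1 in adipose tissue. Batch 2 alone gave 672 lower in muscle. In batch 1, ARG2 in liver was 0.18, ABAT in muscle 0.00478, CXCL8 in adipose -0.0358 and RNF165 in adipose 0.11. With the libraries before quality control, fast fibre genes in muscle turned to 0.39 (MYBPC2 in muscle), 0.59 (MYL1 in muscle), 0.41 (MYLPF in muscle) and 0.0486 (TNNI2 in muscle). The left-out muscle libraries were the LCLF libraries of animals 12218 and 15545. Myocyte markers took 20.1% of counts in that of 12218 but 0.0435% in that of 15545, where adipocyte markers took 1.12%. The library of 15545 therefore held little muscle RNA, and its effect on these values was not tested apart. The counts at a log2 change of at least 0.5 moved too. In liver the 126 lower were 603 with the libraries before quality control and 216 with no low-count filter, and batch 1 gave 466 higher. In muscle the 83 higher were 245 with no block, 255 with no block and all libraries, 159 with DESeq2, 126 with limma-voom, 137 with no low-count filter and 12 in batch 1, and the 16 lower were 10 with no block, 8 with DESeq2 and 3 in batch 1. In adipose tissue the 117 lower were 215 with no low-count filter. Without the animals in doubt (limma-voom), the calls of IL1RN in liver, MYH2 and ECI1 in muscle and FABP5 in adipose tissue, members that moved against their lists, ended, and they held in limma-voom with all animals. With an estimated correlation 6 lists passed in liver, 0 in muscle and 0 in adipose tissue (2 and 4 at an unadjusted p under 0.05).

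With score changes of other cell types as covariates, 25 genes were higher and 19 lower in liver, 275 and 308 in muscle, and 415 and 396 in adipose tissue. The median log2 size of called genes went from 0.214 to 0.0893 in liver, 0.179 to 0.114 in muscle and 0.156 to 0.0704 in adipose tissue, and standard errors grew by a median factor of 1.88, 1.11 and 1.4, so both smaller changes and wider errors ended calls. Some genes below belong to the scores themselves. The values turned to -0.0715 (CCL5 in liver), -0.058 (CD4 in liver), -0.0499 (CDH19 in liver), -0.0117 (CDH5 in liver), -0.0528 (IFIT3 in liver), -0.0269 (NCAM1 in liver), -0.094 (RELN in liver), -0.036 (TIE1 in liver) and -0.24 (VCAM1 in liver). They turned to -0.0515 (CD3E in muscle), -0.0493 (CD4 in muscle), 0.00686 (CDH5 in muscle) and -0.0345 (NKG7 in muscle). They turned to -0.0049 (ALAS2 in adipose), 0.0216 (CLDN5 in adipose), -0.0331 (COL14A1 in adipose), -0.0122 (COL1A1 in adipose), -0.0481 (COL1A2 in adipose), 0.10 (FASN in adipose), -0.0114 (HBB in adipose), -0.11 (HEMGN in adipose), -0.00759 (PTGS2 in adipose), 0.00206 (ROBO4 in adipose) and -0.13 (S100A8 in adipose). None of the turned values passed the test.

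At the real library sizes and numbers of animals, 74%, 63% and 68% of simulated changes of 0.2 were recovered in liver, muscle and adipose tissue. Depth was not varied apart from the number of animals and their spread, so how far depth limits small changes was not tested.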

Other observations

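The genes and lists of the next 2 paragraphs and the label of the clock genes as shifted were chosen after their values were seen, while the tests of a shared macrophage response, of the clock phase and of the spread between animals were written before their results.

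In adipose tissue, 3404 of 16827 genes were lower, among them some of glucose use and lipid storage whose lists did not pass. SLC2A4, the insulin-responsive glucose transporter, fell by 0.24 ± 0.09, and MLXIPL, a carbohydrate-sensing factor of lipogenesis, by 0.52 ± 0.09. Of 14 genes of glucose and insulin signalling, 5 fell and 0 rose, with the same counts adjusted over the list alone. CIDEA, a lipid droplet protein, fell by 0.67 ± 0.11 and SOAT1, which esterifies cholesterol, by 0.39 ± 0.06, among 6 of 16 lipid droplet genes that fell and 1 that rose, also adjusted over the list alone (camera adjusted p = 0.38 for the glucose and 0.221 for the lipid droplet list).

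In liver, proliferation genes went both ways. TOP2A rose by 1.05 ± 0.15 and MKI67 by 0.81 ± 0.12, while BIRC5 fell by 0.40 ± 0.07 and PLK1 by 0.28 ± 0.05, and of 14 cell cycle genes 6 rose and 3 fell, also adjusted over the list alone. CETP, which moves cholesterol esters between lipoproteins, rose by 1.18 ± 0.11. HK2, a hexokinase, rose by 0.90 ± 0.10 and FADS2, a fatty acid desaturase, by 1.04 ± 0.21. Of 15 genes of endoplasmic reticulum stress, 6 fell and 1 rose, also adjusted over the list alone. Of 19 acute phase genes 5 fell and 1 rose, or 3 and 1 adjusted over the list alone, and the cell cycle, stress and acute phase lists did not pass camera.

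Of 16 clock genes, 7 fell and 1 rose in liver, also adjusted over the list alone. In muscle 1 fell and 3 rose, or 2 and 4 adjusted over the list alone, and in adipose tissue 8 fell and 4 rose, or 8 and 5 adjusted over the list alone. The list did not pass camera in liver (adjusted p = 0.12), muscle (0.569) or adipose tissue (0.644). The mean change of the phase score was -0.28 ± 0.11 in liver (n = 84), -0.18 ± 0.11 in muscle (n = 95) and -0.40 ± 0.09 in adipose tissue (n = 95). Across animals its change correlated between liver and adipose tissue (r = 0.536, rho = 0.497, 0.492 without the 2 farthest animals, 0.822 in batch 1 and 0.529 in batch 2), liver and muscle (r = 0.599, rho = 0.585, 0.57, 0.725 and 0.63) and adipose tissue and muscle (r = 0.708, rho = 0.694, 0.694, 0.732 and 0.7). Each permutation p was 1e-05, the smallest possible, and 5e-05 adjusted over 15 relations. A candidate explanation is that an animal's biopsies were taken at another time of day at 2 years than at 0 years, and the smaller of the correlations with adipose tissue, 0.536, met that prediction. Sampling times were not used here, and a clock shifted by the diet in all tissues of an animal was not tested.

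A hypothesis was that animals with a strong macrophage response in liver also had one in adipose tissue. The score changes correlated at r = 0.222 (95% interval 0.00489 to 0.419, n = 82), with a permutation p of 0.045 and 0.11 adjusted over 15 relations, and rho = 0.231 (p = 0.037, adjusted 0.11). Without the 2 farthest animals r was 0.182, and within batches 1 and 2 it was -0.17 (n = 13) and 0.239 (n = 69). The relation failed the correction, so no relation is not excluded. The interval, which is not adjusted, runs from a negligible relation to a moderate one.

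Another hypothesis was that the diet widened the spread between animals in liver. By the rank version, 9 of 9914 genes had a wider spread at 2 years and 4 a narrower one, which met the prediction of more wider than narrower genes, but a binomial test of 9 against 4 gave p = 0.267, and genes are not independent. The version on the values gave 552 wider and 68 narrower. At an unadjusted p under 0.05 the rank version gave 954 genes in both directions together. In muscle the counts were 39 and 0 by ranks, with 949 at an unadjusted p under 0.05, and 361 and 27 by values, and in adipose tissue, in the other direction, 10 and 98 by ranks, with 1619 at an unadjusted p under 0.05, and 32 and 179 by values. The same binomial test gave p = 3.64e-12 in muscle and 2.65e-19 in adipose tissue. The standard deviation was larger at 2 years for 67.4% of genes in liver, 61.6% in muscle and 37.3% in adipose tissue. The median standard deviation between animals went from 0.329 to 0.355 in liver, 0.411 to 0.429 in muscle and 0.315 to 0.303 in adipose tissue. The rule for reading this test was changed after the 9 and 4 were seen and then restored.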
